A study of Penicillium roqueforti with 6 samples.

How the data were processed

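RNA was sequenced from conidia of Penicillium roqueforti harvested under 6 conditions, at culture ages of 3, 5, 7 and 10 days at 25 °C and, for cultures of 7 days, also at 15 and 30 °C. Per the labels' protocols, cultures grew on malt extract agar, and stranded libraries of polyadenylated RNA were sequenced on an Illumina NextSeq instrument. HISAT2 2.1.0 and Cuffdiff are named per the submitters' processing notes. The version of Cuffdiff, the genome build and the annotation are not given in the sources used here.

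The authors' deposited table gives 1 FPKM value per gene and condition for 9762 genes, with a column of q-values for each of the 15 pairs of conditions. The design text names 3 replicates per condition. The authors' FPKM columns combine them, so that no spread, number of replicates or test could be computed here. Depth per library is unknown from FPKM, and no interval that needs it is given. The authors' deposited q-values reach down to 0.00070. They measure the spread between the authors' replicates, and nothing in the labels says whether these came from separate cultures, so it may be technical. The table also flags genes at a q of 0.05 with a change of 4-fold and an expression of 50, and recomputing that rule gave the same genes.

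Genes carry the identifiers of the table, printed without the shared prefix and the transcript ending. None of them matched the reference gene table (0 of 9762 against 9809 reference genes), so genes are described by the Pfam domains (7335 genes) and Gene Ontology terms (4830 genes) of the deposited table, which also assigns 281 genes to secondary metabolism clusters. A domain name describes a family and not the tested function of a gene. No coordinates were used. Reads shared between related genes were not assessed, and values of multigene families such as sugar transporters and glycoside hydrolases carry that uncertainty. A value of 0 means that a gene is listed at 0, as 39 genes were in every condition.

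A gene was called where its q in the authors' deposited table was at or below 0.05, with the direction taken from the FPKM values. A count by size alone took genes with a change of 2-fold or more on the log2(FPKM + 1) scale and at least 5 FPKM in one of the conditions compared. The pseudocount of 1 FPKM understates the change of weakly expressed genes. The 7 comparisons were days 5 and 3, days 7 and 5, days 10 and 7, days 10 and 3, and, at day 7, 15 and 25 °C, 30 and 25 °C, and 30 and 15 °C. Comparisons that use the same condition, such as those of 15 and of 30 °C with 25 °C, share its values and are not independent. A steady course meant a rise, or a fall, at each step among genes with at least 5 FPKM in one condition, set beside the number expected if the 24 orders of 4 values or the 6 orders of 3 values were equally frequent. Correlations between comparisons are across genes, as Pearson's r and Spearman's rho. The overlap of calls is given beside the product of both numbers of calls divided by the number of genes.

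There were 26 gene lists, defined by Pfam accessions or keywords and fixed before the data were examined. They covered heat shock proteins and chaperones, trehalose and polyol metabolism, pigment, hydrophobins, conidiation stress proteins, velvet-domain regulators, antioxidant enzymes, ribosomal proteins, ribosome biogenesis, DNA replication and cell cycle, histones, hyphal growth, cell wall synthesis and remodelling, glycoside hydrolases, secreted and vacuolar peptidases, sugar and amino acid transporters, secondary metabolism, glyoxylate and fatty acid oxidation, glycolysis and fermentation, the tricarboxylic acid cycle and respiration, desaturases and sterols, proteasome and ubiquitin, autophagy, and light response. Of the 42 cell wall genes 32 are also among the 168 glycoside hydrolases, so these lists are not independent. The list of ribosomal proteins matched 0 genes and was replaced by one of 127 genes defined after the annotation was seen, which is not among the 25 lists counted. For each list with at least 3 members, the median log2 change was placed among the medians of 10000 random lists of the same size matched on mean expression in 10 bins, and a list was called outside where it fell below percentile 2.5 or above percentile 97.5. That percentile describes these values and is not a p-value. The numbers of lists given by chance take genes as drawn independently, and genes of one list, family or cluster may change together. A count of members adjusted over the list alone could not be made, because the table gives no unadjusted p.

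Genes named in the text followed a rule fixed before the data were examined. For day 10 against day 3, 15 against 25 °C and 30 against 25 °C, it took the 10 largest rises and the 10 largest falls among called genes with at least 10 FPKM in one condition and a described domain. It added up to 4 members of each list with the largest change, members of the trehalose, polyol, pigment, hydrophobin and conidiation lists, and the 10 genes with the highest mean.

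Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, no minimum or a minimum of 20 FPKM, a minimum of 4-fold, a q of 0.01, rescaling of each column to a common sum or by the median ratio to the geometric mean, and lists restricted to members with a mean of at least 5 FPKM. The authors' stricter flag, the combination of q and size, the sum rescaling of lists, steady courses and correlations, and the alternative settings of single named genes were added after seeing the data. Other alternatives fixed at the outset, which need replicate columns or counts, could not be run on these values. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

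The calculations were tested on simulated data. Gene counts used the day 3 values with an assumed noise, and lists used the measured changes from day 3 to day 10. Of 9762 simulated genes, all 100 raised 4-fold and all 100 lowered 4-fold were recovered by size, and 1 of 9562 unchanged genes was called. The simulated 4-fold change lay well past the 2-fold minimum, and the noise was assumed and not measured. These gene counts therefore follow largely from the settings of the simulation. They check the calculation and give no rate of missed or false calls for the measured values. Of 1000 random lists of 30 genes, 6.3% lay outside the central 95%. Lists shifted by 0.5 on the log2 scale were found outside in 73 of 100 draws, and lists shifted by 1 in 100 of 100.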

Results

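Polyadenylated RNA was profiled in conidia, the asexual spores, of the blue-cheese mould Penicillium roqueforti. The fungus was grown on malt extract agar, and conidia were harvested under 6 conditions. Cultures grown at 25 °C were harvested at 3, 5, 7 and 10 days, and cultures of 7 days were also grown at 15 °C and at 30 °C. The design addresses how the transcripts in the spore differ with culture age and growth temperature. The labels give the age of the culture and not that of the conidia. Maturation is used below for the course with culture age. The design text names 3 replicates per condition, and the table analysed here gives 1 authors' FPKM value for each of 9762 genes in each condition. FPKM count fragments per kilobase of transcript, here normalised between libraries in a way that the sources do not state. Replicates are not given singly. There is therefore no replicate spread to set beside a value. Whether a difference exceeded the replicate error is taken from the q-values of the authors' deposited table, and "rose", "fell" and "changed" are used only where that q was at or below 0.05. The read depth behind the values is unknown, since FPKM do not carry it. Log2 changes are on the log2(FPKM + 1) scale.

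A small part of the transcripts held much of the summed FPKM. FPKM are scaled by transcript length, so these are not shares of reads or of RNA mass. The most abundant transcript in every condition was g7694, which encodes a protein with a Grg1 domain, named after a fungal gene induced by glucose starvation; it stood at 59389 FPKM at day 3 and at 173077 FPKM at day 10. Other leading transcripts at day 3 were the hydrophobin g3485 at 34079 FPKM, the small heat shock protein (HSP20) gene g1728 at 31902 FPKM, the hydrophobin g5509 at 25064 FPKM and g57, which has no Pfam domain, at 22964 FPKM. Hydrophobins coat the spore surface and make it water-repellent. The 100 most abundant genes, ranked anew in each condition, held 39.8% of all FPKM at day 3 and 50.1% at day 10. The sum over all genes was 1430369 FPKM at day 3 and 2095356 FPKM at day 10.

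Between day 3 and day 10 at 25 °C, transcripts of small conidial stress proteins, of autophagy genes and of several enzymes rose, while transcripts of abundant hydrophobins, of a pigment enzyme and of many genes for ribosome assembly, respiration, wall synthesis and remodelling, and sugar uptake fell. The largest rises among genes with a described domain were those of the aegerolysin gene g3236, from 19.7 to 1270.0 FPKM, and of the multicopper oxidase gene g3235, from 11.9 to 576 FPKM. The Con-6 gene g8873, of a family first known from conidiating fungi, rose from 4.01 to 174 FPKM, the cyanovirin-like (CVNH) gene g4008 from 104 to 1896 FPKM and the zinc transporter (Zip) gene g3247 from 19.98 to 393 FPKM. The largest falls among called genes were those of g4047, a gene with a hypoxia-induced (HIG_1_N) domain that went from 39.4 FPKM to a listed 0, and of the sugar transporter g7701, from 447 to 25.8 FPKM. The cerato-platanin gene g8137 fell from 315 to 23.96 FPKM, and the cellulase-family gene g4927 from 2319.7 to 219 FPKM. In the authors' deposited table, 2062 genes were higher and 2051 lower at day 10 at a q of 0.05, together 42.1% of all genes. By size alone, 1353 genes were higher and 1363 lower by 2-fold or more. These directions hold relative to the authors' scaling: when every column was set to the same sum, the median gene moved by -0.52 on the log2 scale, and the 2-fold counts became 625 higher and 2520 lower.

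**Figure D1:**
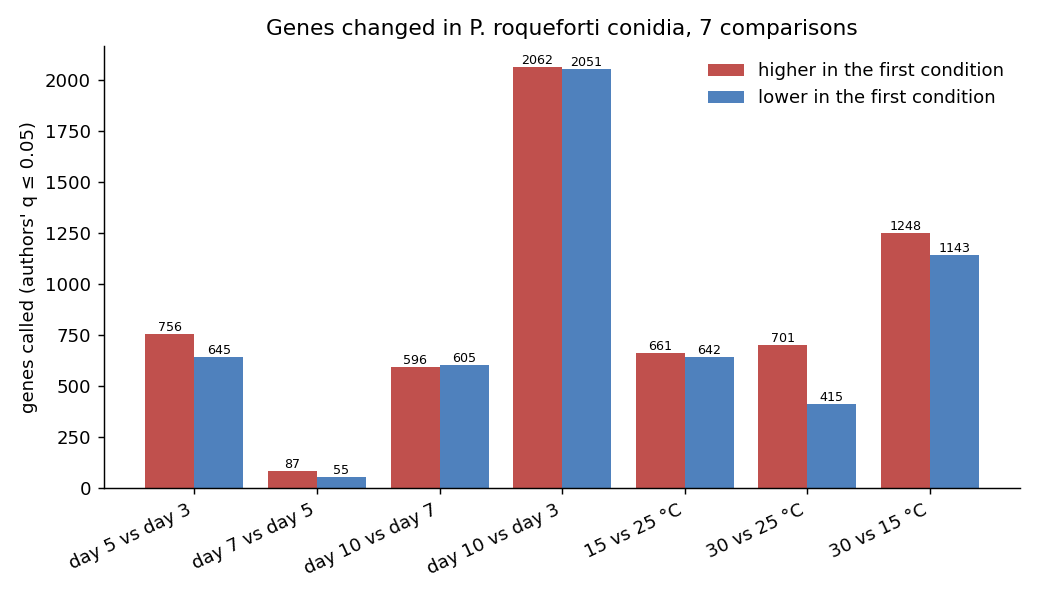
Number of genes called at a q of 0.05 in the authors' deposited table for each of 7 comparisons on the x axis, with red bars for genes higher and blue bars for genes lower in the first-named condition. The comparison of day 10 with day 3 had 2062 higher and 2051 lower genes, and that of day 7 with day 5 had 87 and 55.

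The conidiation stress protein list, with 4 members, stood farthest from other genes. Its median log2 change was 4.19, at the 100th percentile of random lists matched on expression, and 3 of the 4 members rose. These were g8873, the KGG-repeat gene g8989 (188 to 1796 FPKM) and the Con-6 gene g9316 (248 to 533 FPKM). The other member, the KGG gene g2891, was at 0.923 FPKM at day 3 and 716 FPKM at day 10, but its q in the authors' deposited table was 0.263. Of the 8 genes of trehalose metabolism, the pathway of a main storage and protectant sugar of fungal spores, 4 rose and none fell, with a median log2 change of 0.63 at percentile 88.7, inside the range of random lists; that median was 0.14 with columns set to the same sum. The trehalose-phosphate synthase family gene g2478 rose from 9.89 to 80.5 FPKM and g9475 from 176 to 363 FPKM. Of 22 autophagy genes 12 rose and 3 fell, at a median of 0.67 and percentile 98.15; g5673 (ATG13) went from 34.8 to 166 FPKM and g2820 (ATG27) from 207 to 730.3 FPKM. With columns set to the same sum that median was 0.12, at percentile 97.84. Among 80 proteasome and ubiquitin genes, 25 rose and 2 fell, at a median of 0.35 and percentile 95.36, inside the range of random lists. That median was -0.20 with columns set to the same sum.

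Of 4 hydrophobin genes 2 fell, the abundant members g3485 from 34079 to 9936 FPKM and g5509 from 25064 to 7026 FPKM, and the list median was -1.10 at percentile 1.59. All 4 velvet-domain genes fell, a family of regulators of conidium formation, at a list median of -1.14 and percentile 1.81; g4507 went from 309 to 113 FPKM, g3766 from 516 to 264 FPKM, g1938 from 25.4 to 9.90 FPKM and g7644 from 24.8 to 11.9 FPKM. Scytalone dehydratase g6392, an enzyme of DHN-melanin synthesis, fell from 3386 to 378 FPKM, and the short-chain dehydrogenase gene g6391 from 3124 to 295 FPKM. The pigment list itself had a median of -0.02 at percentile 23.03. It held 6 genes, of which g6392 was the only one known to act in pigment synthesis. Of the others, 4 were matched through names of the Arp2/3 actin complex and 1 through Alb1, a ribosome-associated domain. Of the 4 genes of the polyol list 1 rose and 2 fell, at a median of -0.47 and percentile 13.71. Mannitol dehydrogenase family gene g7055 fell from 318 to 110.1 FPKM and g9649 from 720.2 to 424 FPKM, and g283, with domains of glycerol-3-phosphate and 3-hydroxyacyl-CoA dehydrogenases, rose from 21.1 to 47.9 FPKM. Of 41 antioxidant genes 11 rose and 11 fell, at a median of -0.34 and percentile 0.41; the thioredoxin-domain gene g951 rose from 551 to 3257 FPKM.

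Of 24 ribosome biogenesis genes 14 fell and none rose, with a median of -0.98 below all 10000 random lists; the pescadillo gene g6340 fell from 43.3 to 13.4 FPKM and fibrillarin g5922 from 151 to 60.6 FPKM. Ribosomal protein genes, a list of 127 matched only after the annotation was seen, had 32 falling and 15 rising at a median of -0.26. For the tricarboxylic acid cycle and respiration, 12 of 26 fell and 2 rose at a median of -0.67 and percentile 0.01, with the ATP synthase subunit gene g290 going from 959 to 354 FPKM. Of 42 genes of cell wall synthesis and remodelling 23 fell and 3 rose, at a median of -0.79. Of these, 32 also belonged to the glycoside hydrolase list, so these lists are not independent, and of the other 10, of chitin and glucan synthase families, 8 fell and 1 rose. The glycoside hydrolase 16 genes g1271 and g8135, members of both lists, fell from 62.6 to 9.90 FPKM and from 110.5 to 21.0 FPKM. Glycoside hydrolases as a whole had 72 of 168 falling and 19 rising, at a median of -0.49, but g7824 (family 17) rose from 108 to 1143 FPKM and the cellulase-family gene g8016 from 109.8 to 1111 FPKM. Sugar transporters had 57 of 160 falling and 18 rising, at a median of -0.45 and percentile 0.10. Secreted and vacuolar peptidases had 11 of 27 falling and 4 rising, at a median of -0.52 and percentile 1.14; the aspartic peptidase g23 rose from 1723 to 12740.2 FPKM and the aminopeptidase g3512 fell from 231 to 26.0 FPKM. The peptidase list came inside the range of random lists, at percentile 6.87, when only members with a mean of at least 5 FPKM were kept. All 297 genes annotated as proteases in the deposited table had 59 rising and 69 falling, at a median of -0.07 and percentile 27.62, inside that range.

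The remaining lists lay inside the range of random lists. Heat shock proteins and chaperones had 15 rising and 12 falling of 61 at percentile 2.66; the DnaJ gene g7257 rose from 66.3 to 369 FPKM, whereas the HSP70 genes g5693 and g9397 fell from 328 to 52.8 FPKM and from 3517 to 1563 FPKM. DNA replication and cell cycle genes had 12 rising and 27 falling of 67 at percentile 4.99, and the DNA polymerase family gene g4249 rose from 107 to 1183 FPKM. Hyphal growth genes, included with the aim of marking hyphae carried over in a harvest, had 4 rising and 12 falling of 34 at percentile 15.69. The most abundant members of that list were of tubulin-cofactor, dynein, tubulin and kinesin families, which are not specific to hyphae. Its percentile can therefore neither show nor exclude hyphae. None of 8 histone genes was called, at percentile 15.22. Secondary metabolism backbone genes had 9 rising and 14 falling of 36 at percentile 12.26, with the polyketide synthase g6432 falling from 892 to 138 FPKM. Amino acid transporters had 14 rising and 30 falling of 84 at percentile 4.52, glycolysis and fermentation genes 6 and 6 of 22 at percentile 9.55, and desaturase and sterol genes 4 and 6 of 24 at percentile 8.77. Glyoxylate and fatty acid oxidation genes had 9 rising and 6 falling of 39 at percentile 63.12. The light response list had 2 rising and 1 falling of 3 at percentile 75.04, and its rhodopsin gene g8394 rose from 4013 to 11168 FPKM. In all, 11 of 25 lists lay outside the central 95% of random lists, where chance gives 1.25.

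**Figure D2:**
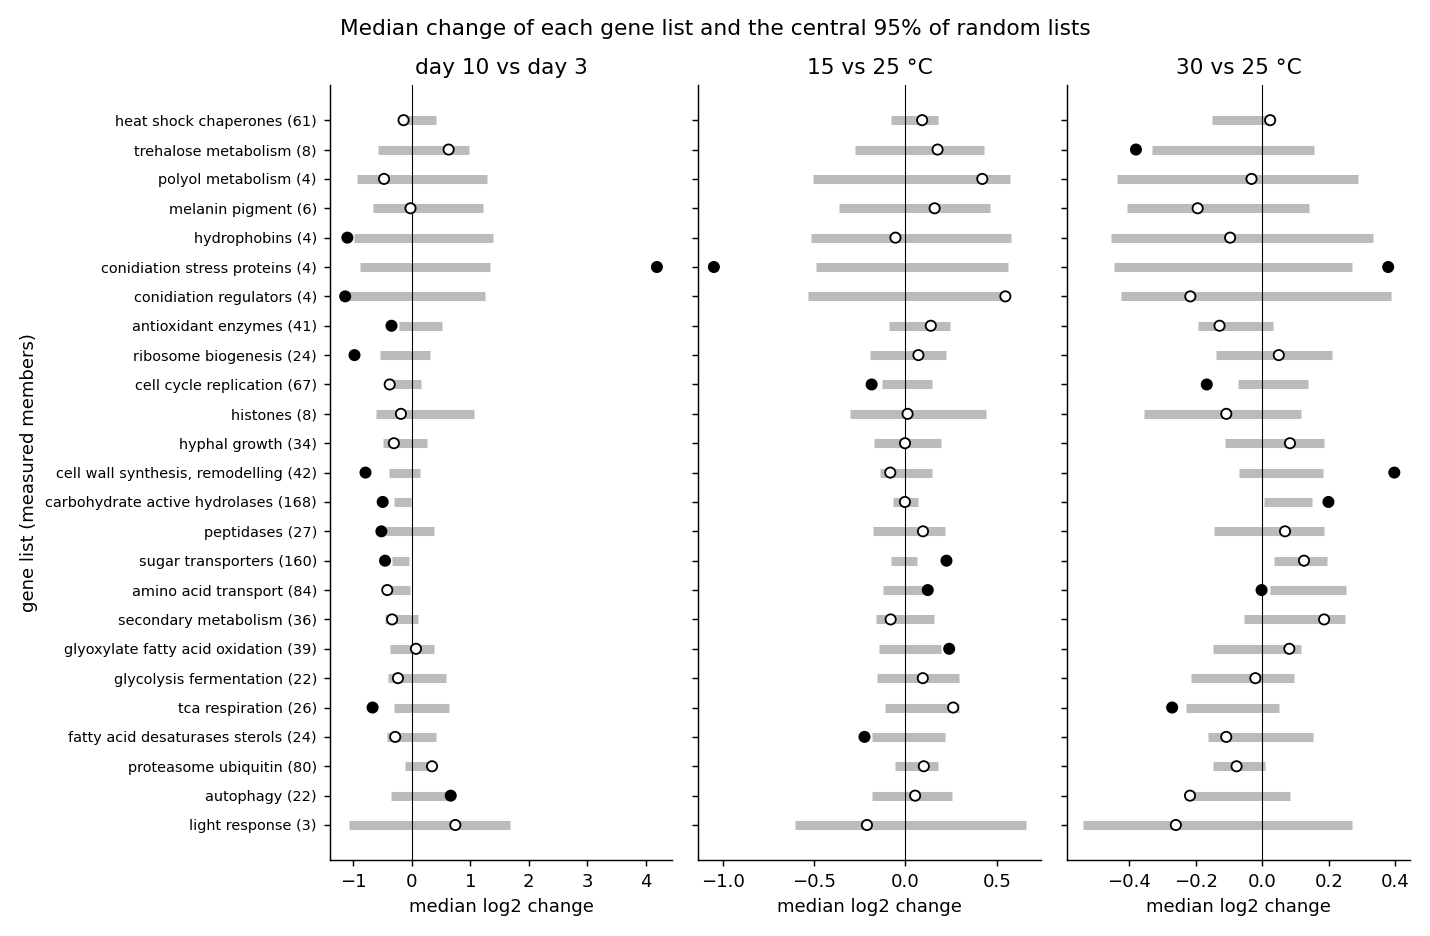
Median log2 change (x axis) of each of 25 gene lists (y axis, measured members in brackets) for day 10 against day 3, 15 against 25 °C and 30 against 25 °C, drawn as points that are filled where outside the grey bar, the central 95% of 10000 random lists matched on expression. The x scales differ between panels, and the conidiation stress protein list has medians of 4.19, -1.05 and 0.38.

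Most calls between successive ages fell in the first and the last interval. From day 3 to day 5, 756 genes rose and 645 fell in the authors' deposited table, from day 5 to day 7 only 87 rose and 55 fell, and from day 7 to day 10, 596 rose and 605 fell. Conidiation stress proteins rose at every step, 3, 2 and 3 of the 4 members in turn, with list medians of 1.93, 1.14 and 1.11 at percentiles 99.99, 100 and 99.98; g8873 stood at 4.01, 29.0, 66.5 and 174 FPKM on days 3, 5, 7 and 10. Of 24 ribosome biogenesis genes 5 fell at the first step (list median -0.45) and 3 at the last (list median -0.48), and none rose at either, with a median of -0.01, a mean of 0.02 and no call between days 5 and 7. Of 42 cell wall synthesis and remodelling genes 20 fell and 2 rose at the first step, none was called at the second, and 12 fell and 2 rose at the last. Scytalone dehydratase g6392 stood at 3386, 1279.6, 1350.0 and 378 FPKM over the 4 ages. In total, 12, 3 and 10 of the 25 lists lay outside the range of random lists at the successive steps. At the middle step, which took no part in the selection, 74.2% of the 4113 genes called between days 3 and 10 moved toward their day 10 value, by a median of 0.14 on the log2 scale. Over the whole course 1158 genes were higher and 861 lower in value at each of the 3 steps and by 2-fold or more in all, without regard to q. They made up 74.2% of the 2721 genes that differed by 2-fold between the end points. With columns set to the same sum, 542 genes were higher and 1664 lower in this way, which turns the balance. Without the fold minimum, 2174 genes were higher and 1838 lower at every step, against 340.75 for each if the 4 ages came in random order. With columns set to the same sum, the 2-fold genes that were higher and lower went from 373 and 249 to 234 and 370 between days 3 and 5, and from 167 and 281 to 24 and 724 between days 7 and 10; the median gene moved by -0.16 and -0.35.

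**Figure D3:**
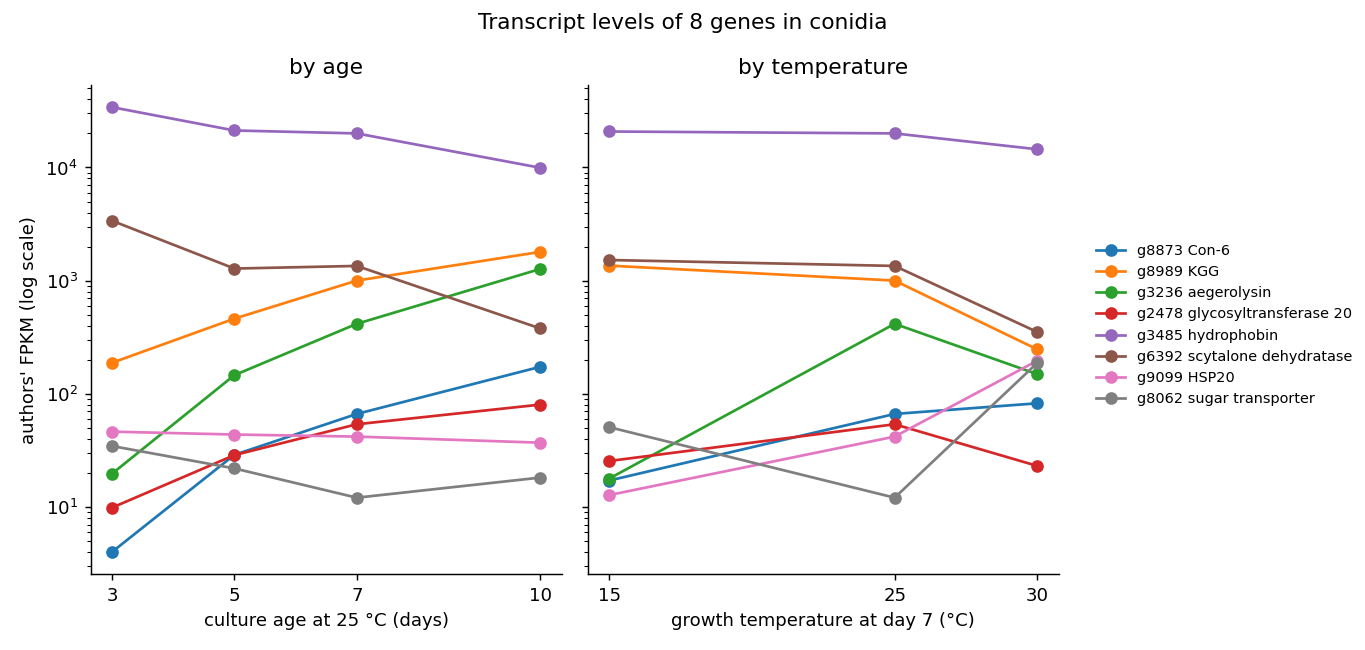
Authors' FPKM (y axis, log scale, no replicate values) of 8 genes against culture age at 25 °C (left x axis, days) and against growth temperature at day 7 (right x axis, °C), with a line joining the values of each gene. The Con-6 gene g8873 climbs from 4.01 to 174 FPKM with age and stands at 17.2 FPKM at 15 °C, while the sugar transporter g8062 is highest at 30 °C with 188 FPKM.

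Conidia grown at 15 °C for 7 days had less transcript of several genes that rose with culture age than conidia grown at 25 °C. They had more transcript of many sugar transporters and of glyoxylate cycle genes. The aegerolysin gene g3236 stood at 17.8 FPKM at 15 °C and 416 FPKM at 25 °C, g3235 at 22.8 and 147 FPKM, the arylsulfotransferase gene g8946 at 25.8 and 158 FPKM, and g3247 at 17.9 and 112 FPKM, and all 4 fell. The largest rises among genes with a described domain were those of the transporter g4756, from 1.14 to 33.1 FPKM, of the prenyltransferase-family (UbiA) gene g3678, from 0.825 to 17.6 FPKM, and of the alcohol dehydrogenase gene g841, from 170.5 to 1313 FPKM. In the authors' deposited table, 661 genes were higher and 642 lower at 15 °C. By size alone, 286 were higher and 356 lower by 2-fold or more.

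Sugar transporters rose more often than they fell at 15 °C, 25 against 8 of 160, at a median of 0.22 that exceeded all random lists; g2513 went from 78.0 to 312 FPKM, g1988 from 49.5 to 167 FPKM and g7701 from 170.0 to 429.7 FPKM. Of 39 glyoxylate and fatty acid oxidation genes 8 rose and 1 fell, at a median of 0.24 and percentile 99.43, with isocitrate lyase g7567 going from 314 to 714 FPKM and malate synthase g8085 from 309.6 to 718 FPKM. These are the enzymes specific to the glyoxylate cycle. Glycolysis and fermentation genes had 4 rising and 1 falling of 22 at percentile 58.08, and respiration genes 1 rising of 26 at percentile 94.41, both inside the range of random lists. The added list of 127 ribosomal protein genes had 5 rising and 1 falling, at a median of 0.22 and percentile 97.96. Amino acid transporters had a median of 0.12 at percentile 98.89 with 5 rising and 5 falling of 84. Below the range of random lists lay conidiation stress proteins (median -1.05, percentile 0.14, 1 of 4 falling, g8873 from 66.5 to 17.2 FPKM), DNA replication and cell cycle genes (median -0.18, percentile 0.27, 2 of 67 rising and 4 falling) and desaturase and sterol genes (median -0.22, percentile 1.03, 2 of 24 falling). Fatty acid desaturase g1940 fell from 171 to 80.5 FPKM. The desaturase and sterol list came inside the range at a pseudocount of 5 FPKM, at percentile 3.89. The KGG gene g2891 stood at 0.818 FPKM at 15 °C and 201 FPKM at 25 °C, with a q of 0.278 in the authors' deposited table. Chaperones went both ways, 6 rising and 5 falling of 61. The HSP70 gene g8798 fell from 61.8 to 7.86 FPKM, the HSP20 gene g9099 from 42.0 to 12.8 FPKM and g7257 from 173 to 54.0 FPKM, while HSP90 g7455 rose from 272 to 558 FPKM and HSP70 g9397 from 1929 to 4024 FPKM. Trehalose-phosphate synthase family gene g2478 fell from 53.9 to 25.5 FPKM, and mannitol dehydrogenase family gene g7055 rose from 159 to 322 FPKM. The catalase gene g8514 rose from 28.1 to 96.9 FPKM, aconitase g5326 from 629.6 to 1379 FPKM and the polyketide synthase g6432 from 192 to 560.5 FPKM. The hydrophobins g3485 and g5509, at 20781 and 12543 FPKM, were not called. Of 25 lists 6 lay outside the range of random lists.

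At 30 °C, conidia had more transcript of a set of sugar transporters, glycoside hydrolases, chitinase-family genes and chaperones than at 25 °C, and less of the pigment gene g6392 and of several other transporters. The NLPC_P60 peptidase-family gene g5882 rose from 19.8 to 1026 FPKM, and the sugar transporters g8792, g8092, g8062, g8663 and g4169 from 2.31 to 112, from 3.78 to 134, from 12.1 to 188, from 6.81 to 88.9 and from 3.21 to 41.4 FPKM. The glycoside hydrolase genes g9304 (family 71) and g4323 (family 31) rose from 0.138 to 18.6 FPKM and from 1.97 to 35.9 FPKM. Falls included those of the GPI-anchored protein gene g7397, from 63.9 to 3.81 FPKM, the RING-finger gene g6167, from 127 to 11.8 FPKM, and the sugar transporter g3827, from 24.9 to 2.104 FPKM. In the authors' deposited table, 701 genes were higher and 415 lower at 30 °C, and by size alone 459 were higher and 217 lower by 2-fold or more. With columns set to the same sum the median gene moved by 0.14 on the log2 scale.

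Of the 42 cell wall synthesis and remodelling genes 13 rose and 2 fell at 30 °C, at a median of 0.40 above all random lists. Of the 32 shared with the glycoside hydrolase list 10 rose and 2 fell, and of the 10 genes of chitin and glucan synthase families 3 rose and none fell. The chitinase-family (glycoside hydrolase 18) genes g5245 and g7 rose from 30.5 to 282 FPKM and from 67.0 to 277 FPKM, and the family 16 gene g4304 from 33.7 to 149 FPKM; all 3 are in both lists. Glycoside hydrolases had 40 of 168 rising and 8 falling, at a median of 0.20 and percentile 99.88. The cellulase-family gene g4927 fell from 916 to 124 FPKM. In this comparison the hyphal growth list had a median of 0.08 at percentile 76.75, with 1 rising and 1 falling of 34. Sugar transporters changed in both directions, 37 rising and 23 falling of 160, at percentile 62.93. Those that fell included g651, from 130.2 to 21.0 FPKM, and g7959, from 207 to 46.8 FPKM. The glycosyltransferase 34 genes g9527 and g7245 fell from 312 to 37.4 FPKM and from 238 to 32.3 FPKM, scytalone dehydratase g6392 from 1350.0 to 351 FPKM and g6391 from 1174 to 243 FPKM.

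Of 61 chaperone genes 8 rose and none fell at 30 °C, at a median of 0.02 and percentile 97.04, inside the range of random lists, and at percentile 97.74, outside it, with only members of at least 5 FPKM on average. The HSP20 gene g9099 rose from 42.0 to 197 FPKM, the HSP70 genes g5693 and g8798 from 78.99 to 335 FPKM and from 61.8 to 124 FPKM, HSP90 g7455 from 272 to 647 FPKM and its activator Aha1, g3666, from 85.5 to 181 FPKM. The most abundant of them, g1728, was not called, at 43908 FPKM at 25 °C and 40729 FPKM at 30 °C. Trehalose metabolism had a median of -0.38 at percentile 1.16 with 1 of 8 falling, g2478 from 53.9 to 23.1 FPKM. The conidiation stress list had 1 rising and 1 falling of 4, its median of 0.38 at percentile 98.96 and its mean of -0.10 having opposite signs; g8989 fell from 1002 to 247 FPKM, and g2891 rose from 201 to 363 FPKM with a q of 0.0444 in the authors' deposited table. Respiration genes had a median of -0.27 at percentile 0.73 with 1 of 26 rising, and DNA replication and cell cycle genes one of -0.17 at percentile 0.01 with 2 of 67 rising and 1 falling. The DNA replication and cell cycle list was also below the range at 15 °C, against the same 25 °C values. At 30 against 15 °C its median was -0.008 at percentile 27.5, inside the range. A deviation of the 25 °C values is therefore not excluded. Amino acid transporters had a median of -0.00 at percentile 0.41, with 12 of 84 rising and 7 falling and a mean of 0.03; the median was 0.09 with columns set to the same sum. That list came inside the range of random lists, at percentile 4.56, when only members with a mean of at least 5 FPKM were kept. The added ribosomal protein list, with none of 127 called, had a median of -0.00 at percentile 100; that median was 0.14 with columns set to the same sum. The amino acid permease g1571 rose from 3.90 to 38.2 FPKM. Mannitol dehydrogenase family genes parted, g7055 rising from 159 to 446 FPKM and g9649 falling from 594 to 224 FPKM. The catalase g8514 fell from 28.1 to 6.87 FPKM. The prenyltransferase gene g6473 and the non-ribosomal peptide synthetase gene g6475, of the same annotated secondary metabolism cluster, rose from 26.5 to 213 FPKM and from 22.2 to 109.6 FPKM. Of 25 lists 7 lay outside the range of random lists.

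Across the full temperature range, 1248 genes were higher and 1143 lower at 30 °C than at 15 °C in the authors' deposited table. HSP20 g9099 stood at 12.8, 42.0 and 197 FPKM at 15, 25 and 30 °C, and HSP70 g8798 at 7.86, 61.8 and 124 FPKM. Catalase g8514 went the other way, at 96.9, 28.1 and 6.87 FPKM, and the sugar transporter g2513 stood at 312, 78.0 and 32.7 FPKM. Glycoside hydrolases had 48 of 168 rising and 14 falling (percentile 100), the overlapping list of cell wall synthesis and remodelling 17 of 42 rising and 3 falling (percentile 99.96) and respiration 10 of 26 falling and 1 rising (percentile 0.21). Conidiation stress proteins (median 1.43, percentile 99.96), sugar transporters (median -0.02, mean 0.05, percentile 0.05) and amino acid transporters (median -0.03, percentile 0.51) also lay outside the range of random lists. Their calls were split, with 1 rising and 1 falling of 4, 31 and 29 of 160, and 11 and 16 of 84. With columns set to the same sum the medians of the transporter lists were 0.13 and 0.09. By size alone 832 genes were higher and 555 lower by 2-fold or more, and 1039 and 343 with columns set to the same sum, which moved the median gene by 0.19. A steady course over the 3 temperatures with 2-fold or more in all was seen upward for 625 genes and downward for 452, again without regard to q, and without the fold minimum for 1929 and 2248 genes, against 1385.5 for each in random order. With columns set to the same sum, the 2-fold steady courses numbered 833 upward and 264 downward.

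The design also allows the changes with age and with temperature to be set against each other across genes, which are not independent replicates. The temperature comparisons share no condition with that of days 3 and 10. The change from day 3 to day 10 and the difference of 30 from 15 °C had a Pearson r of 0.27 and a Spearman rho of 0.22 over 8402 genes. Of 1295 genes called in both in the authors' deposited table, 946 went the same way, with 494 rising in both where independent lists would share 263.61, and 452 falling in both where they would share 240.14. The parts of the temperature range differed. For 15 against 25 °C r was -0.39 and rho -0.34 over 8251 genes, and 704 of 806 genes called in both, or 87.3%, went in opposite directions. They included 448 genes that rose with age and were lower at 15 °C, where independent lists would share 135.61, among them g3236, g23 (5529 FPKM at 25 °C and 1654 FPKM at 15 °C), g7824 (656 and 162 FPKM) and g951 (2251 and 904 FPKM). For 30 against 25 °C r was -0.01 and rho -0.07 over 8360 genes, with 303 genes going the same way and 295 the opposite way. Genes that fell with age were over-represented on both sides, 209 lower at 30 °C where independent lists would share 87.19 and 207 higher where they would share 147.28. Of genes that rose with age, 94 were higher at 30 °C where 148.07 would be shared, and 88 lower where 87.66 would be. These expected numbers take all genes as equally likely to be called, which was not tested.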

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

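The alternatives added after seeing the data were the authors' stricter flag, the combination of q with size, the sum rescaling of lists, steady courses and correlations, and the settings of single named genes; the others were planned. No paired analysis was possible because the columns carry one value per condition and no replicate numbers. For the same reason, leaving out replicates, a replicate block and the count-based alternatives were not run, and depth sets no stated limit since FPKM do not show it. Counts by q are given in the order days 5 and 3, 7 and 5, 10 and 7, 10 and 3, then 15 and 25 °C, 30 and 25 °C, and 30 and 15 °C. Called genes at a q of 0.05 numbered 1401, 142, 1201, 4113, 1303, 1116 and 2391 in the authors' deposited table. A q of 0.01 left 774, 53, 547, 724, 666 and 1576, leaving out days 10 and 3, which stayed within 1.5 times. The authors' flag left 24, 2, 20, 391, 49, 58 and 136, and a q of 0.05 with 2-fold and 5 FPKM left 567, 46, 404, 2629, 572, 616 and 1301. Each of these thresholds is stricter by construction. Genes past 2-fold by size alone numbered 622, 70, 448, 2716, 642, 676 and 1387. A 4-fold minimum left 40, 7, 34, 557, 98, 108 and 279, again by construction. A pseudocount of 5 FPKM, which shrinks changes of low genes, left 402, 36, 262, 418 and 414 for days 5 and 3, 7 and 5, 10 and 7, 15 and 25 °C and 30 and 25 °C. A minimum of 20 FPKM, with fewer genes, left 38 for days 7 and 5 and 413 for 30 and 25 °C. Rescaling to a common sum gave 748 for days 10 and 7. The column sums were 2095356 FPKM at day 10 and 1615951 FPKM at day 7, so a common sum lowers every day 10 value against day 7. Why the sums differ was not tested. All other totals stayed within 1.5 times, as did the numbers of lists outside and the totals of genes with a steady course. Their directions moved more. By common sum the 1158 higher and 861 lower genes of the age course became 542 and 1664, and the 625 and 452 of the temperature course 833 and 264. The column sums went from 1430369 FPKM at day 3 to 2095356 FPKM at day 10, and from 1680253 FPKM at 15 °C to 1464243 FPKM at 30 °C. A common sum thus moves all values down with age and up with temperature. The 625 became 410 with a pseudocount of 5 FPKM and 386 with a minimum of 20 FPKM. The correlation of age with 30 against 15 °C, 0.269, was 0.241 and 0.308 with pseudocounts of 0.1 and 5 FPKM, 0.338 with 20 FPKM and 0.298 with the common sum. With 15 against 25 °C, -0.388 became -0.361 and -0.431 with these pseudocounts and -0.456 with 20 FPKM. With 30 against 25 °C, -0.0123 became 0.0104 with 20 FPKM and 0.0121 with the common sum; the cause of these moves was not tested. Of 728 alternative medians of single lists 41 changed sign, 30 of them by common sum, and 33 of the 41 belonged to lists inside the range of random lists. Further, 10 came inside that range and 7 went outside it. The 8 sign changes of lists outside the range are as follows. Those that reversed between days 10 and 7 were antioxidant enzymes (0.00927) and the added ribosomal proteins (0.00798) by median ratio, and proteasome (-0.147) and autophagy (-0.0188) by common sum. By common sum, amino acid transporters (0.0909) and the added ribosomal proteins (0.139) reversed at 30 against 25 °C, and sugar transporters (0.128) and amino acid transporters (0.0909) at 30 against 15 °C. All 8 went the way in which the rescaling moved the median gene. Of 460 alternative log2 values for named genes none of a called gene reversed, and 241 moved by 0.05 or more. A pseudocount cannot change a sign, which covers 115 values at 0.1 FPKM and 115 at 5 FPKM. Many of the genes were also picked for large changes, so the absence of reversals says little about robustness.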

Other observations

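Of the tests below, those on weakly expressed genes, on g7694, on the other transcripts, on an earlier point at 30 °C and on hyphae were chosen after the result was seen. The sets in this paragraph and the next were chosen after the data were seen too, from the annotation of the deposited table. Of 297 Pfam families scanned for days 10 and 3, 18 lay outside the central 99% of random lists, where chance gives 2.97, and phosphorelay genes were among them. Of 17 genes with a histidine kinase (HisKA) domain 12 rose and none fell between days 3 and 10 in the authors' deposited table, at a median of 1.05 and percentile 100, and of 19 with a response regulator domain 14 rose and none fell, at a median of 0.93. These domains form the phosphorelays through which fungi sense osmotic and oxidative stress. Both sets may share genes and are not counted as independent. The Gene Ontology term for phosphorelay signal transduction had 21 genes, of which 15 rose and none fell. Annotated transcription factors had 112 rising and 70 falling of 418, at a median of 0.14 and percentile 100. With columns set to the same sum the median gene moved by -0.52, so the direction of that transcription factor median depends on the scaling. Of 695 genes with a predicted secretion signal 231 fell and 102 rose with age at a median of -0.33, 68 fell and 54 rose at 15 °C at a median of -0.03, and 31 fell and 122 rose at 30 °C at a median of 0.22. Of 170 Gene Ontology terms scanned for days 10 and 3, which can share genes, 28 lay outside the central 99%, where chance gives 1.7 for independent genes. One of them was proton-coupled ATP synthesis, of whose 11 genes 9 fell and none rose, at a median of -1.24.

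Of 27 annotated secondary metabolism clusters, 8, 6 and 7 lay outside the central 95% of random lists with age, at 15 °C and at 30 °C, where chance gives 1.35. That number holds for independent genes, and genes of one cluster may change together. All 3 genes of cluster 18, which holds g6473 and g6475, rose at 30 °C, at a median of 2.25. Of the 11 genes of cluster 4, 7 rose with age (median 1.28), 4 rose at 15 °C (median 0.49) and 8 rose at 30 °C (median 1.07). Both temperature comparisons use the same 25 °C values, so the rises at 15 and 30 °C are not independent. Cluster 27 had 3 of 11 falling at 15 °C (median -0.78, percentile 0.01). At 30 °C 354 genes differed from all 4 ages at 25 °C at a q of 0.05 in the authors' deposited table, 315 of them higher, and these included 26 sugar transporters and 18 glycoside hydrolases. At 15 °C 194 genes were higher and 80 lower than at all 4 ages. The KGG gene g2891 was the only one of 100 genes with 8-fold or more and 50 FPKM between days 3 and 10 that the authors' deposited table did not call, with 0.923 and 716 FPKM.

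Conidia grown at 15 °C differed from those at 25 °C against the direction of maturation. An expression-dependent distortion of the columns is argued against by the median correlation within 10 bins of mean expression, -0.447, with bins from -0.639 to -0.146, and unstable values of weak genes by a correlation of -0.598 over 2139 genes with a mean of at least 100 FPKM. A delayed course alone, within the ages sampled, is argued against as well, since 28.55% of the 1303 called genes had a 15 °C value inside the range of the 4 ages, where 560 lay above it and 371 below. Of the 704 genes called in both comparisons in opposite directions, 49.29% lay inside that range, 162 above it and 195 below. Delay as a part of the cause stays open. Conidia at 15 °C had 966 calls against day 5 at 25 °C, fewer than the 1303 against day 7, 1873 against day 3 and 2876 against day 10. A hypothesis that remains open and untested is that growth at 15 °C may combine slower maturation with a response to temperature itself. Harvest and library batches are not given, and temperature and any such batch cannot be separated.

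The 100 most abundant transcripts of each age took a larger share of all FPKM with age, from 39.8% to 50.1%. The 10 most abundant carried most of it, from 16.2% to 25.3%, while ranks 11 to 100 went from 23.5% to 24.8%. Transcripts were ranked anew at each age, so these sets need not hold the same genes. A single transcript is argued against as the whole cause, since without g7694 the share still rose by 8.41 percentage points, from 37.3% to 45.7%. Whether abundant transcripts gained or the others were lost cannot be told apart. Genes outside the 100 had a median log2 change of -0.00283 on the authors' scale, and a relative scale holds no absolute amount. Loss of less stable transcripts in ageing conidia may be one contributor, and no spike-in or RNA yield was analysed here to test it.

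Conidia at 30 °C had more transcript of glycoside hydrolase and cell wall genes, groups in which most called members fell with age at 25 °C. An earlier point of the maturation course is argued against as the whole cause, since across the 135 genes with at least 5 FPKM among the members of either list, which share 32, the changes at 30 °C and with age had an r of 0.13 (95% interval -0.04 to 0.29, treating genes as independent) where that cause needs a negative one, and 19 of the 43 members that rose at 30 °C were called above all 4 ages. As a partial cause it stays open, since ages before day 3 were not sampled. Of the 43, 23 fell with age and 4 rose, but falls prevailed among all members. With age 15 of the 32 shared genes fell and 2 rose, 8 and 1 of the 10 other wall genes, and 57 and 17 of the 136 other hydrolases. The count among the 43 is therefore weak support for a link with age. Hyphae carried over in the harvest stay open too. The hyphal growth list stood at percentile 76.75 with a baseline median of 22.0 FPKM over 34 genes, which could hide a small share. Its most abundant member, the tubulin-cofactor gene g4173, named after its values were seen, stood at 1158.8 FPKM at 25 °C and 1012.8 FPKM at 30 °C. The list is led by cytoskeleton families that are not specific to hyphae, so it cannot decide. A response of the wall to temperature may also contribute and was not tested.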
